A study of Mus musculus with 6 samples.

How the data were processed

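RNA was taken from neurospheres on day 6 of culture, per the labels' protocols. The spheres were grown from embryonic forebrain progenitors in medium with bFGF and EGF, each at 20 ng/ml, and with 0.2% BSA and 2% B27, and libraries were made from 3 µg of RNA with an Illumina kit whose use of strand is not stated. The labels name the dorsal cortex as the source and the lateral walls of the lateral ventricles as the dissected part. Which of these was used cannot be told from the labels. Each library was assigned to WT or KO and given its replicate number from its title. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.16.1 and the mm10 build, and the settings of these tools and the gene annotation are not given in the sources used here.

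The deposited table held 54532 genes with whole-number read counts per gene for the 6 libraries, which the authors had not normalised, per the file headers and the column sums. It also held FPKM values per gene and library, made by the authors from gene length and library total. The headers of the FPKM columns also carry the word count, and their unit was taken from the values. Multiplying each deposited FPKM by gene length and library total gave back the deposited count within 0.05 reads in all but 4 of 327192 values, 148038 of which were above 0. These 4 values belonged to Ctnnb1, Fzd7 and Neurog2 in KO libraries, and the counts were analysed as deposited, with the counts implied by the FPKM as an alternative. Gene names, biotypes and coordinates were those of the table, and overlapping genes were found from these coordinates. GENCODE M21 gave the GC content, with 99.9% of tested genes matched.

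Total counts ran from 16764480 to 21983659 per library, at which 3 reads correspond to 0.136 to 0.179 CPM. The share of counts taken by the 10 most counted genes was 3.57% to 5.85%. Libraries of 1 group correlated at Spearman's rho of 0.965 to 0.992 across genes and libraries of different groups at 0.898 to 0.957, and no pair agreed within sampling noise (chi-square per degree of freedom of at least 17.8), so none was treated as a repeat deposit of another.

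KO was compared with WT in 1 fit of all 6 libraries without covariates. Counts were normalised by TMM (factors 0.961 to 1.04), genes were kept by the filterByExpr defaults, which left 16606, and edgeR 4.0.16 in R 4.3.3 was used for the two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are normalised by TMM. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic, and was not fitted separately. The biological coefficient of variation was 26.5%. An exact permutation test of 3 against 3 cannot go below p = 0.1, so single values were not tested that way. For the principal components, log2 CPM had a prior count of 2.

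There were 35 gene lists, fixed before the data were examined, with 734 genes, all found in the table and 621 tested. The 32 lists with at least 3 tested members, apart from the list of Xist and Y-linked genes, which only describes the libraries, were tested with camera on the edgeR fit data at a preset correlation between genes of 0.01 (limma 3.58.1), with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, a rotation test of whether a list's genes move on balance in 1 direction, were alternatives. Of the 17 lists past the threshold 0 held with an estimated correlation. Some genes stand in more than 1 list.

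The genes named were fixed by a rule before the data were examined. They are Ash2l, the 10 genes of each direction with the largest change and the 5 with the lowest p among protein-coding genes past the threshold with a mean of at least 2 CPM and groups that did not overlap, the up to 4 tested members of each list with the lowest p (6 for the Wnt and COMPASS lists), and Xist and Y-linked genes. Some genes taken for naming are not reported here, and counts over genes or lists include them. Genes named outside the rule are said to have been chosen after their values were seen. The annotated spans of Rnd2, Entpd2, Cnp, S100b, Wnt5b, Rspo1, Tap1, Kdm5a, Eng, Draxin, Npc1, Mest, Col18a1 and Syn1 overlap another gene with more than 10% of their mean count. So does that of Fgfr2, whose span in the table covers several other genes. Reads of these genes can be shared with the overlapping gene, and how many are shared was not measured.

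The alternatives changed 1 choice at a time, except that DESeq2 and the FPKM scales brought their own scaling and gene filter (19749 and 15727 genes tested) and limma-voom its sample weights. They were RLE size factors, library totals only, no expression filter, a filter of 1 CPM in 3 libraries, no genes of the X, Y or mitochondrial chromosomes, DESeq2 1.42.0, limma-voom with quality weights, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5, a test against a 1.5-fold change, an adjusted p of 0.01, protein-coding genes only, a second term in the edgeR fit that sets WT 3 and KO 3 against the other 4 libraries (a block for replicate number 3), and each library left out in turn.

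The tests were tried on simulated counts for KO against WT with the means and library sizes of the 16606 genes, 200 of them changed. The edgeR test found 27% of the genes changed 2-fold and 68% of those changed 4-fold, and 3 of its 98 calls were unchanged genes. DESeq2 found 56% and 81%, with 24.7% of its calls unchanged genes, limma-voom 22% and 67%, and limma on log2(FPKM + 1) 19% and 66%. In simulated lists of 25 genes, camera called the raised list with a preset and with an estimated correlation (adjusted p = 1.38e-44 and 0.00291) and 0 of the unchanged lists. The simulated genes were drawn independently of each other, whereas the estimated correlation was 0.763 for the G1/S list and 0.932 for the G2/M list. The simulation therefore cannot show how camera performs on lists of correlated genes.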

Results

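Messenger RNA was sequenced from primary neurospheres, free-floating colonies grown from neural progenitor cells, of mouse embryos at E14.5, mid-gestation. The embryos were wild type (WT) or carried a conditional knockout of Ash2l (KO) driven by D6-Cre, a Cre recombinase transgene active in the dorsal forebrain. ASH2L is a shared subunit of the COMPASS family of complexes, which methylate lysine 4 of histone H3. The spheres had been grown for 6 days with EGF and bFGF. There were 3 WT libraries, numbered 3, 6 and 7 by the submitters, and 3 KO libraries, numbered 1, 2 and 3. Total counts over genes were 17575641, 20759023 and 21983659 in WT 3, WT 6 and WT 7, and 16764480, 18212574 and 21007543 in KO 1, KO 2 and KO 3. The labels do not say that the libraries of a group came from separate embryos or cultures, so the p-values measure the spread between these libraries, which may be partly technical. The comparison asked which transcripts differ between KO and WT spheres of forebrain progenitors, and how genes of the Wnt pathway, which the series title names, behave among them. The labels leave unclear which part of the forebrain was dissected.

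Ash2l itself (ENSMUSG00000031575, chromosome 8 from 25815996 to 25847694 on mm10) was measured at 113 ± 3.55 CPM in WT and 95.9 ± 8.41 CPM in KO (SD, n = 3 each). All 3 KO libraries lay below all 3 WT libraries, and the log2 fold change of KO over WT was -0.24 (SE 0.10), which did not pass the threshold (adjusted p = 0.119, edgeR quasi-likelihood test, Benjamini-Hochberg). KO libraries thus held 84.9% of the WT level of Ash2l reads. The deleted exons are not given in the sources used here, and a count over the whole gene includes reads from exons that a deletion leaves in place, so these values cannot show how many cells had recombined. Among the other COMPASS subunits, Dpy30 (log2 fold change 0.88, SE 0.11), Wdr5 (0.61, SE 0.10), Paxip1 (0.55, SE 0.11) and Hcfc1 (0.42, SE 0.12) rose, and none of the 18 tested members fell. The call of Hcfc1 ended without WT 3, WT 6, WT 7, KO 1 or KO 2, and that of Paxip1 without WT 6, WT 7 or KO 2. Over the 18 members alone, 3 passed, and the list as a whole did not (camera adjusted p = 0.524, and adjusted p = 0.76 with an estimated correlation).

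The KO spheres differed from the WT spheres in a large part of the transcriptome, with proliferation genes higher and glial genes lower. Cyclin D1 (Ccnd1), the G1 cyclin and a known Wnt target, rose from 35.6 ± 1.44 to 752 ± 156 CPM (SD, n = 3 each), 21.1-fold. The protease-activated receptor gene F2rl1 had the largest rise among the named genes, at 63.4-fold (log2 fold change 5.99, SE 0.62), from only 0.161 ± 0.154 CPM in WT. Angiotensinogen (Agt), an astrocyte product, was 77.2-fold lower (log2 fold change -6.27, SE 0.33), and Enpp6 and Mag, genes of differentiating and myelinating oligodendrocytes, were 75.8-fold and 63.2-fold lower (log2 fold changes -6.24 and -5.98). These values depended on single libraries, at 7.01 for F2rl1 without WT 3, and at -8.79 for Enpp6 and -7.97 for Mag without KO 3, the KO library with the most reads of both.

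In the edgeR quasi-likelihood test 4812 of 16606 tested genes passed an adjusted p of 0.05, 2240 higher and 2572 lower in KO, which was 29% of the genes tested. Of these, 1224 were higher and 1266 lower by more than 2-fold. The groups did not overlap in 4789 of the 4812 genes, and in 48.6% of all tested genes, where chance gives 10%. On principal components of log2 CPM, component 1 held 69.9% of the variance and placed the WT libraries at -85.7, -81.7 and -25.5 and the KO libraries at 53.5, 62.6 and 76.8. WT 3 lay nearest to the KO libraries, and the count of changed genes was 6641 without WT 3, 2178 without WT 6 and 2449 without WT 7, and 2889, 2516 and 4266 without KO 1, KO 2 and KO 3. Of the 144 genes taken for naming that passed, 96 did so whichever library was left out. They were picked largely by low p or large change in these data, which favours that outcome. Of all 4812 calls, 44.8% were kept without WT 6 and 93.7% without WT 3, the lowest and highest shares.

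**Figure D1:**
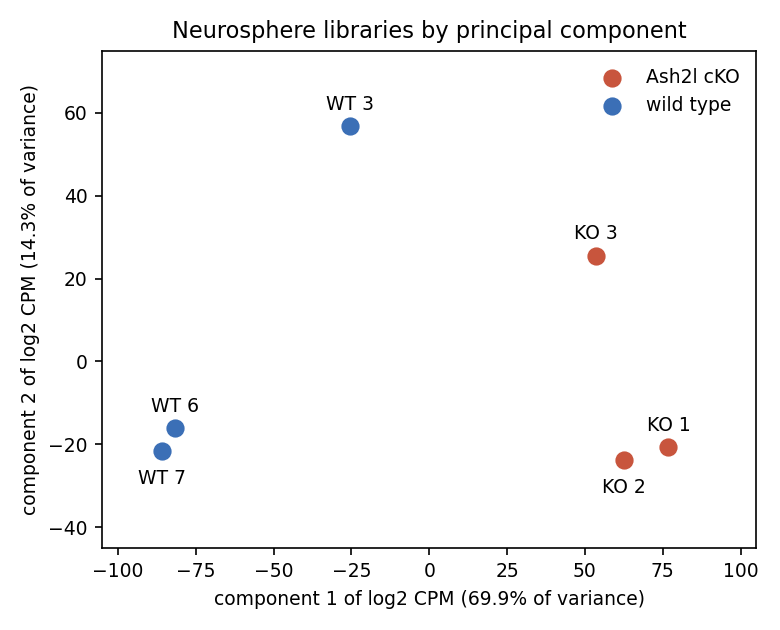
Each point is 1 of the 6 libraries on components 1 and 2 of log2 CPM, with the percent of variance on each axis (WT blue, KO red). The 3 KO libraries sit between 53.5 and 76.8 on component 1 and the 3 WT libraries between -85.7 and -25.5, with WT 3 apart from WT 6 and WT 7 on both components. On component 2 WT 3 (56.7) and KO 3 (25.5) lie apart from the other 4 (-23.7 to -16.2).

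The genes with the lowest p among those that rose were Tubb6, a beta tubulin (log2 fold change 2.82, SE 0.12), Ccnd1 (4.40, SE 0.19), the galectin gene Lgals1 (3.45, SE 0.15), and the replication licensing genes Mcm2 (3.02, SE 0.15) and Cdt1 (3.13, SE 0.18). By fold, F2rl1 and Ccnd1 were joined by Anxa3 (4.98, SE 0.54), Car3 (4.90, SE 0.75), Lamc3 (4.83, SE 1.11), Cd93 (4.77, SE 0.46), Adamts14 (4.72, SE 0.37) and BC030867 (4.28, SE 0.29). Raet1d and Ifi203 also ranked there, but both belong to families of near-identical genes between which reads can be split, and their values are uncertain. Cd93 and Adamts14 measured only 0.301 and 0.256 CPM in WT, so their folds rest on few WT reads. The genes with the lowest p among those that fell were Tmeff2 (-2.43, SE 0.10), Agt, the sodium-calcium exchanger Slc24a3 (-2.22, SE 0.13), Emp2 (-2.86, SE 0.17) and Col27a1 (-2.62, SE 0.17). By fold, those that fell most included Agt, Enpp6, Mag, myelin basic protein (Mbp, -4.83, SE 0.78), the connexin Gjc3 (-4.79, SE 0.56), the ectonucleotidase Entpd2 (-4.68, SE 0.41), Bcas1 (-4.49, SE 1.09), Gfap (-4.32, SE 0.71) and Cldn10 (-4.21, SE 0.61). The call of Bcas1 ended without WT 6, KO 1 or KO 2, and that of Lamc3 without WT 6 or WT 7. Some folds moved by more than 1.5-fold when 1 library was left out, to 2.98 for Lamc3 without KO 1, to 5.66 for Anxa3 without WT 6, and without KO 3 to -6.63 for Bcas1, -6.04 for Mbp and -4.82 for Cldn10. Adjusted p-values of the genes in this paragraph lay between 0.000324 and 0.0277 (edgeR quasi-likelihood, Benjamini-Hochberg).

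Every tested gene of both cell cycle lists rose in KO. The 30 genes of G1/S and DNA replication had a median log2 fold change of 2.56, a median of 5.88-fold, with Cdc6, a loader of the replicative helicase, at 3.71 (SE 0.23) and Mcm3 at 3.08 (SE 0.19). The 30 genes of G2/M and mitosis had a median of 3.17, or 8.98-fold, and a median of 3.82 without WT 3. Among them were the mitotic kinases Cdk1 at 3.34 (SE 0.34) and Plk1 at 3.48 (SE 0.37), Foxm1 at 3.04 (SE 0.29) and Birc5 at 2.99 (SE 0.25). Mki67, a marker of cycling cells that was singled out after its values were seen, rose from 38 ± 25.7 to 383 ± 54.4 CPM (SD, n = 3 each), a log2 fold change of 3.34, and 4.03 without WT 3. All 30 members of each list also passed when adjusted over the list alone. The lists passed camera with a preset correlation (adjusted p = 1.48e-57 and 1.63e-34), and not with an estimated one (adjusted p = 0.44 with an estimated correlation for both). Both passed fry (adjusted p = 0.00832 for G1/S and 0.0162 for G2/M). Within WT, the mean log2 CPM of the G2/M genes was 4.25 in WT 3 against 3.00 in WT 6 and 2.71 in WT 7, and in KO it lay between 6.51 and 6.88.

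Genes of both glial lineages fell. Of 18 oligodendrocyte lineage markers 14 fell and none rose, with a median log2 fold change of -3.06, among them Cnp (-3.42, SE 0.36), Ugt8a (-3.28, SE 0.36) and the progenitor receptor Pdgfra (-1.93, SE 0.23). Mbp went from 641 ± 272 to 22.5 ± 22.3 CPM and Cnp from 860 ± 98.7 to 80 ± 39.3 CPM (SD, n = 3 each). Of 18 astrocyte markers 13 fell and none rose, with a median of -2.24, among them S100b (-3.60, SE 0.40), clusterin (Clu, -2.22, SE 0.26) and connexin 43 (Gja1, -2.41, SE 0.29). Adjusted over the list alone, 14 oligodendrocyte and 16 astrocyte markers fell, and 1 astrocyte marker rose. Both lists passed camera (adjusted p = 4.21e-09 for oligodendrocytes and 6.89e-12 for astrocytes), but neither did with an estimated correlation (adjusted p = 0.44 with an estimated correlation for both). Fry passed both (adjusted p = 0.022 for oligodendrocytes and 0.0236 for astrocytes). WT 3 had lower astrocyte markers than the other WT libraries, at a mean log2 CPM of 7.37 against 8.47 and 8.64, with KO between 5.72 and 6.10. KO 3 kept more of the oligodendrocyte markers than KO 1 and KO 2, at 5.46 against 3.61 and 4.25.

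**Figure D2:**
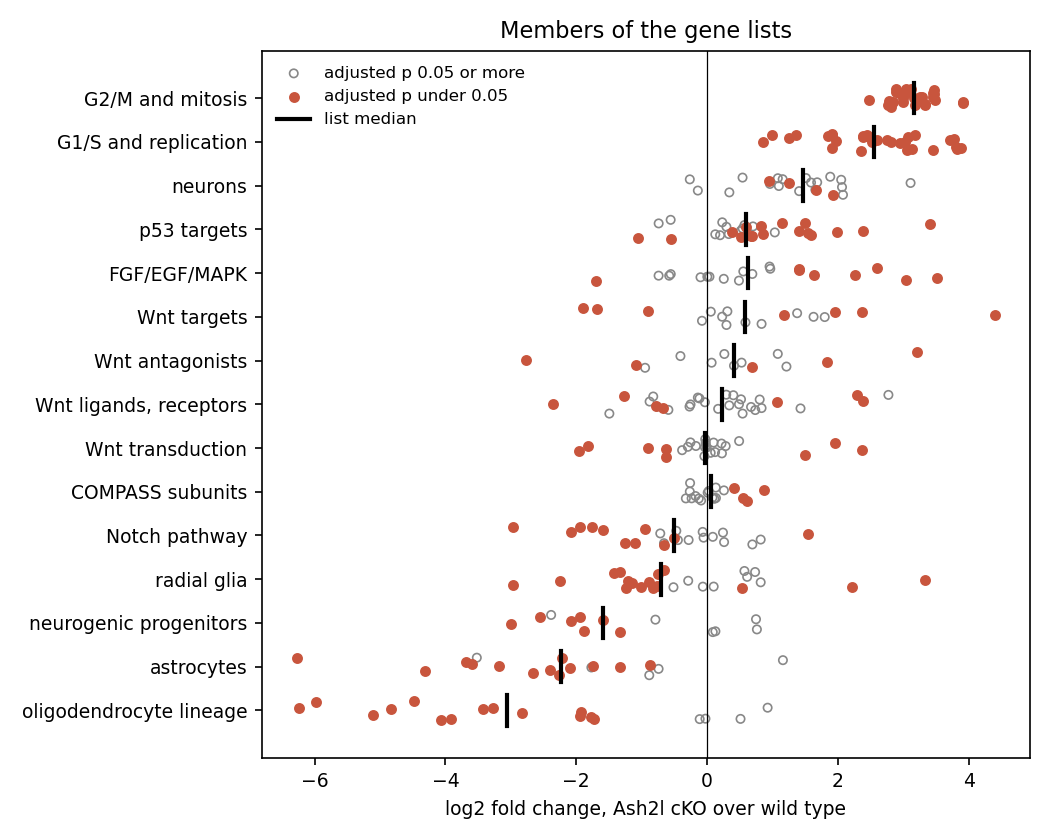
Each point is the log2 fold change of KO over WT of 1 gene of a list (filled, adjusted p under 0.05; open, not), and the black bar is the list median. All 60 cell cycle genes lie to the right of 0, and the oligodendrocyte and astrocyte medians lie at -3.06 and -2.24.

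Progenitor genes moved in both directions. Of 24 neural stem cell and radial glia markers, 13 fell and 3 rose, with a median log2 fold change of -0.70. Pax6, a transcription factor of cortical radial glia, fell by 1.24 (SE 0.10), Hes5 by 2.97 (SE 0.38) and Id4 by 2.24 (SE 0.30), whereas the intermediate filament gene Nes rose by 2.21 (SE 0.26). The list also holds Mki67, which is a proliferation gene. Of 13 genes of intermediate progenitors and early neurogenesis 7 fell, with a median of -1.59, including Rnd2 (-3.00, SE 0.21), Gadd45g (-1.89, SE 0.26), the Notch ligand Dll1 (-1.59, SE 0.28) and Mfng (-2.09, SE 0.38). Of 23 Notch pathway genes 10 fell and 1 rose, with Hes5, Hey1 (-1.76, SE 0.24), Mfng and Dll1 leading. Adjusted over the list alone the counts were 13 lower and 3 higher for radial glia, 9 lower and 1 higher for neurogenic progenitors, and 11 lower and 1 higher for Notch. The lists passed camera (adjusted p = 0.0158, 0.000227 and 0.00366 in that order), and lost the call with an estimated correlation (adjusted p = 0.644, 0.44 and 0.44 with an estimated correlation). By fry the neurogenic progenitor and Notch lists passed (adjusted p = 0.022 and 0.0236) and radial glia did not (adjusted p = 0.0565). Neurog2, a proneural factor, stood at -2.38 (SE 0.81) and did not pass (adjusted p = 0.065, edgeR quasi-likelihood, Benjamini-Hochberg). It measured 41.1, 47.4 and 27.1 CPM in WT 3, WT 6 and WT 7, and 1.56, 3.13 and 17.3 CPM in KO 1, KO 2 and KO 3. It passed without KO 3 (-4.01, adjusted p = 0.00496), without a filter (adjusted p = 0.00979), with limma-voom (adjusted p = 0.00403), on both FPKM scales (adjusted p = 0.0272 and 0.0357) and with a block for replicate number 3 (-3.01, adjusted p = 0.0184). The deposited count of Neurog2 in KO 3 was 15 reads below the count that the deposited FPKM gives.

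Neuronal markers passed camera as a list higher in KO (adjusted p = 0.000672), though not with an estimated correlation (adjusted p = 0.652 with an estimated correlation) or by fry (adjusted p = 0.111). Of 22 markers 4 rose, the growth cone gene Gap43 (log2 fold change 1.67, SE 0.44), Bcl11b (1.92, SE 0.55), synaptophysin (Syp, 1.25, SE 0.37) and Stmn3 (0.94, SE 0.28), and the median was 1.46. Adjusted over the list alone, 0 of the 22 passed, and each of these 4 calls ended when WT 6, WT 7, KO 1 or KO 2 was left out. The calls of Gap43, Syp and Stmn3 ended without KO 3 too. Without WT 3 Gap43 stood at 2.38 and Bcl11b at 2.67. Tubb3, singled out after its values were seen, was at 241 ± 172 CPM in WT and 639 ± 130 CPM in KO (SD, n = 3 each) and did not pass (adjusted p = 0.0636, edgeR quasi-likelihood, Benjamini-Hochberg), except with a block for replicate number 3 (adjusted p = 0.0223). The mean log2 CPM of these markers was 6.80 in WT 3 against 5.12 and 4.81 in WT 6 and WT 7, and 6.93 to 7.57 in KO, and the median log2 fold change was 2.27 without WT 3.

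Genes of the Wnt pathway did not move as a block. Among the transcription factors that bind beta-catenin, Tcf7l2 (log2 fold change -1.82, SE 0.18) and Tcf7l1 (-1.96, SE 0.21) fell, while Tcf7 (1.96, SE 0.30) and Lef1 (2.37, SE 0.50) rose, from low levels of 2.28 ± 0.348 and 0.405 ± 0.302 CPM in WT (SD, n = 3 each), Lef1 at 3.16 without WT 6. Of 24 intracellular mediators 5 fell and 3 rose, also when adjusted over the list alone, with Dvl3 (-0.63, SE 0.11) and the corepressor Tle4 (-0.63, SE 0.13) among those that fell. The list did not pass camera (adjusted p = 0.473, and adjusted p = 0.652 with an estimated correlation), and its median of -0.02 and its mean of 0.01 differed in sign. Beta-catenin itself (Ctnnb1) was at 767 ± 85.2 CPM in WT and 643 ± 30.3 CPM in KO and did not pass (log2 fold change -0.25, SE 0.13, adjusted p = 0.184, edgeR quasi-likelihood, Benjamini-Hochberg), except with limma-voom (adjusted p = 0.0372). Its deposited counts in KO 1 and KO 2 were 200 and 500 reads below the counts that the deposited FPKM gives. Ctnnb1, Fzd7, Axin2, Rnf43 and Wnt3 were singled out after their values were seen.

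Of 17 Wnt target and feedback genes, 4 rose and 3 fell. Ccnd1, Tcf7, Lef1 and Bambi (1.18, SE 0.32) rose, and Apcdd1, an inhibitor of Wnt signalling (-1.90, SE 0.24), Sox4 (-0.90, SE 0.19) and Rnf43 (-1.68, SE 0.47) fell, and 6 rose and 3 fell when adjusted over the list alone. The feedback gene Axin2 stood at 36.5 ± 3.37 CPM in WT and 44.8 ± 2.92 CPM in KO (log2 fold change 0.30, SE 0.12) and did not pass (adjusted p = 0.103, edgeR quasi-likelihood, Benjamini-Hochberg). The list passed camera as higher, with a median of 0.59 (adjusted p = 0.0285, and adjusted p = 0.44 with an estimated correlation). It also passed fry (adjusted p = 0.0236). The camera call (edgeR) ended without WT 3 (adjusted p = 0.225) and without KO 3 (adjusted p = 0.0598).

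Of 30 Wnt ligands, receptors and secretion factors, 3 rose and 4 fell, also when adjusted over the list alone. Fzd10 (2.30, SE 0.34), the receptor tyrosine kinase Ror2 (1.07, SE 0.17) and Rspo1 (2.38, SE 0.48, 0.17 CPM in WT) rose, and Wnt5b (-2.35, SE 0.50), the acyltransferase Porcn (-0.67, SE 0.15) and Fzd8 (-0.79, SE 0.21) fell, as did Wnt3 (-1.27, SE 0.35). Fzd7 stood at -0.88 (SE 0.35) and did not pass (adjusted p = 0.096, edgeR quasi-likelihood, Benjamini-Hochberg), and its deposited count in KO 3 was 27 reads below the count that the deposited FPKM gives. Fzd7 passed without a filter (adjusted p = 0.0427), with DESeq2 (adjusted p = 0.0432), with limma-voom (adjusted p = 0.00945) and without KO 3 (-1.33, adjusted p = 0.0143), and stood at -0.58 without KO 2. Among 13 genes listed as secreted or membrane antagonists, Dkk3 (-2.76, SE 0.37) and Draxin (-1.08, SE 0.32) fell. Sfrp5 (3.21, SE 0.82), Sostdc1 (1.84, SE 0.49) and Tmem132a (0.68, SE 0.16), whose place as an antagonist is uncertain, rose, 3 higher and 2 lower also over the list alone. The calls of Ccnd1, Tcf7, Apcdd1, Tcf7l2, Tcf7l1, Dvl3, Fzd10, Ror2 and Dkk3 held whichever library was left out, and those of the other Wnt genes named as changed ended without at least 1 library. Sfrp5 stood at 4.08 without WT 6. Neither list passed camera (adjusted p = 0.735 for ligands and receptors and 0.78 for antagonists, and adjusted p = 0.811 for both with an estimated correlation).

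**Figure D3:**
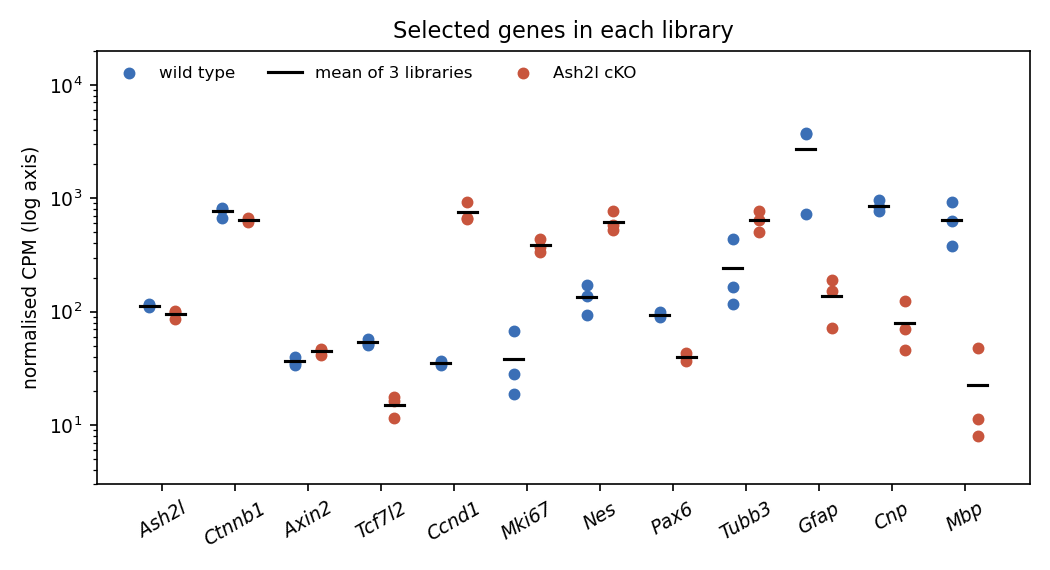
Normalised CPM on a log axis of 12 genes in each of the 6 libraries (WT blue, KO red), with bars at the mean of 3 libraries. Ccnd1 and Mki67 are higher and Tcf7l2, Pax6, Gfap, Cnp and Mbp lower in all 3 KO libraries than in any WT library, and Ash2l and Axin2 differ by a log2 fold change of only -0.24 and 0.30.

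Among growth and stress genes, 6 lists passed camera as higher in KO with a preset correlation, and 0 of them with an estimated one. Of 20 genes of FGF and EGF receptors and MAPK feedback 7 rose and 1 fell. The feedback inhibitors Spry4 (3.51, SE 0.31), Spry1 (2.59, SE 0.27) and Spred2 (1.40, SE 0.15) rose and the receptor Fgfr2 fell by 1.69 (SE 0.14). Of 29 p53 targets 15 rose and 2 fell, with Plk2 (1.59, SE 0.19), Aen (1.14, SE 0.14) and Gtse1 (3.41, SE 0.35), which is also a G2/M gene, among the first, and Sesn1 (-1.05, SE 0.15) among the second. Of 20 genes of the integrated stress response and amino acid synthesis 8 rose and 1 fell, led by Mthfd2 (2.80, SE 0.33) and Asns (1.83, SE 0.24). Of 22 cholesterol synthesis genes 7 rose, including Stard4 (1.15, SE 0.22) and Sqle (0.67, SE 0.16), whose call ended without WT 6, KO 1 or KO 2. Of 21 immediate early genes 8 rose and 1 fell, with Egr3 at 2.64 (SE 0.29), and of 28 hypoxia and glycolysis genes (27 symbols, as Aldoa names 2 gene IDs) 5 rose and 1 fell, with Eno1 at 1.54 (SE 0.29) and Ldha at 1.52 (SE 0.37). Ldha's call ended without WT 6, WT 7, KO 2 or KO 3. Adjusted over the list alone, the counts of higher and lower genes were 11 and 1 for MAPK feedback, 17 and 2 for p53, 10 and 2 for integrated stress, 8 and 0 for cholesterol, 8 and 1 for immediate early genes and 4 and 1 for hypoxia and glycolysis.

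These 6 lists passed camera, with adjusted p = 0.00178 for MAPK feedback, 0.000208 for p53, 0.00289 for integrated stress, 0.00188 for cholesterol, 0.00527 for immediate early genes and 0.0026 for hypoxia and glycolysis. With an estimated correlation none did (adjusted p = 0.44 for MAPK feedback and p53, 0.644 for integrated stress, 0.652 for cholesterol and immediate early genes and 0.672 for hypoxia and glycolysis, each with an estimated correlation). By fry, MAPK feedback and p53 passed (adjusted p = 0.024 and 0.0236) and the others did not (adjusted p = 0.0541 to 0.183). The camera call ended without WT 3 for MAPK feedback (adjusted p = 0.055) and without KO 3 for immediate early genes (adjusted p = 0.112) and for hypoxia and glycolysis (adjusted p = 0.11). The mean log2 CPM of the hypoxia and glycolysis genes was 6.91 in WT 3, above the 6.63 of KO 1, with 5.77 and 6.09 in WT 6 and WT 7 and 7.19 and 7.63 in KO 2 and KO 3.

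Markers of cells from outside the neural lineage were low in WT. Of 12 tested pericyte and meningeal fibroblast markers 3 rose, Acta2 (log2 fold change 3.29, SE 0.46), Lum (4.25, SE 1.23) and Anpep (3.57, SE 1.05), and 8 rose when adjusted over the list alone. Acta2 measured 0.102 CPM in WT, below the level of 3 reads, and 1.05 CPM in KO. KO 1 held most of the reads of both Lum (22.8 CPM against 1.46 and 1.47 in KO 2 and KO 3) and Anpep (5.13 against 0.648 and 0.615). Lum's call ended without WT 3, WT 6 or WT 7, and Anpep's without WT 6, WT 7 or KO 1, and both ended with a block for replicate number 3 (adjusted p = 0.0535 and 0.0538). Without KO 1 Lum stood at 1.73 and Anpep at 1.87. The mean log2 CPM of these markers was 4.59 in KO 1, 1.81 in KO 2 and 2.11 in KO 3, against 1.01 to 1.24 in WT. The list passed camera (adjusted p = 0.0285, and adjusted p = 0.672 with an estimated correlation), and the call ended without WT 3 (adjusted p = 0.214), without KO 1 (adjusted p = 0.0972) and with a filter of 1 CPM in 3 libraries (adjusted p = 0.129). The 13 protein genes of the mitochondrial genome had a median of -0.67, and 3 fell, mt-Nd6 (-0.94, SE 0.21), mt-Nd5 (-0.96, SE 0.24) and mt-Nd4 (-0.80, SE 0.24), of which 2 did over the list alone, and each call ended without any single library except WT 3. The genes mt-Nd5 and mt-Nd6 overlap on opposite strands only between positions 13552 and 13565. The share of counts from the mitochondrial genome was 2.39% in WT 3, 3.30% in WT 6 and 3.25% in WT 7, and 2.28%, 2.15% and 1.95% in KO 1, KO 2 and KO 3. This list passed camera (adjusted p = 0.0317, and adjusted p = 0.668 with an estimated correlation), and the call ended without WT 6 (adjusted p = 0.0805) and without KO 3 (adjusted p = 0.112).

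The remaining lists did not pass camera with the preset correlation. Of 8 genes listed as cyclin-dependent kinase inhibitors 4 rose and 1 fell, with Cdkn3, whose place as an inhibitor is uncertain, at 3.20 (SE 0.31), Cdkn2c at 1.19 (SE 0.16) and Cdkn1a at 1.40 (SE 0.33), and 4 rose and 3 fell over the list alone (camera adjusted p = 0.0779). This list passed without a filter (adjusted p = 0.0326) and without WT 6 (adjusted p = 0.036), KO 1 or KO 2 (adjusted p = 0.0499 for both). Of 22 BMP pathway genes 8 fell and 2 rose, also over the list alone, with Bmpr1b at -1.65 (SE 0.26) and Bmp7 at 1.81 (SE 0.30) (adjusted p = 0.17, and adjusted p = 0.0459 without a filter and 0.0224 with a block for replicate number 3). Among 16 dorsal patterning genes Pax6, Dmrta1 (-2.04, SE 0.45) and Eomes (-2.55, SE 0.57, and -1.93 without WT 3) fell, the same number over the list alone (adjusted p = 0.296). Of 16 ventral patterning genes 2 fell, Gsx2 (-1.81, SE 0.55) among them, and 1 rose, 1 lower and 0 higher over the list alone, and the median of 0.18 and mean of 0.26 were opposite in sign to the direction of the test (adjusted p = 0.921). Kdm5a (-0.63, SE 0.15) fell among 5 demethylases of the same histone mark, also over the list alone (adjusted p = 0.413). Of 11 Hedgehog genes Cdon (0.73, SE 0.15) rose and Ptch1 (-1.46, SE 0.32) fell, also over the list alone, with a median of -0.06 against a mean of 0.08 (adjusted p = 0.921). Of 21 interferon genes Bst2 (1.76, SE 0.30), Ifitm3 (1.83, SE 0.47) and Tap1 (0.83, SE 0.18) rose and Ddx58 (-0.69, SE 0.20) fell, 3 higher and 0 lower over the list alone (adjusted p = 0.473). The call of Gsx2 ended whichever library was left out, and those of Cdkn1a, Dmrta1, Eomes, Kdm5a, Cdon, Ptch1, Ifitm3, Tap1 and Ddx58 without at least 1 library.

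None of 77 ribosomal protein genes passed in the edgeR quasi-likelihood test, whether adjusted over all genes or over the list alone (camera adjusted p = 0.927). None of 11 microglial markers passed either way (adjusted p = 0.295). Their mean log2 CPM was 1.95 in KO 1, -0.14 in KO 2 and -0.11 in KO 3, against -1.08 to 0.46 in WT. Their median log2 fold change of 1.08 fell to 0.11 without KO 1. Of 6 endothelial markers Eng (2.24, SE 0.60), whose call ended without WT 6, WT 7, KO 1 or KO 3, rose and Kdr (-2.07, SE 0.35) fell, also over the list alone (adjusted p = 0.735). Of 10 ependymal and choroid plexus markers Tekt1 (0.99, SE 0.30) rose, a call that ended whichever library was left out, and 0 passed over the list alone (adjusted p = 0.667). None of the 39 Hox genes or the 10 erythroid markers had enough reads to be tested.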

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

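The tests of separate counting, altered values, exchanged labels, admixture and sex in WT 3 were chosen after the results were seen. Checks of sex in the cell cycle and glial genes, of GC content, of depth and of other splits were set before only as kinds of check. The patterns to which those of sex, GC content and depth were applied were first seen in the results. The libraries and gene lists used in these checks were therefore also picked after the results were seen.

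In 4 values, all in KO libraries and 0 in WT, the deposited count lay below the count that the deposited FPKM gives, a difference between the part of the table used for the tests and a part that was not. They were Ctnnb1 in KO 1 (11082 against 11282) and KO 2 (12517 against 13017), Fzd7 in KO 3 (638 against 665) and Neurog2 in KO 3 (365 against 380), between 1.77% and 4.06% of the implied count. A separate counting of the reads for the FPKM would have left many small differences, whereas 2.702 per 100000 values above 0 differed, which argues against it. The library totals behind the FPKM equal the column sums with the 4 implied counts put back in all 6 libraries, which is consistent with counts altered in single values after the FPKM were computed, and how or why that happened cannot be read from the table. With the implied counts the log2 fold changes were -0.23 for Ctnnb1 (adjusted p = 0.241, edgeR), -0.85 for Fzd7 (adjusted p = 0.115) and -2.34 for Neurog2 (adjusted p = 0.0714), none past the threshold, as with the deposited counts, and the same 4812 genes were called, but other settings on the deposited counts passed Ctnnb1 (limma-voom, adjusted p = 0.0372), Fzd7 and Neurog2.

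Cell cycle genes were higher and glial genes lower in KO. Of the libraries only WT 7 had high Y-linked and low Xist counts, and without it the G2/M median log2 fold change was 2.861 and the oligodendrocyte median -3.182, which argues against sex as the whole cause. The trend of the log2 fold change on GC content and gene length stayed between -0.18 and 0.22 for every tested gene with a known GC content, so removing it moved little and left the medians at 3.148 and -3.076, and a trend of that size is too small to be the whole cause. Exchanged group labels cannot be told apart from the deposited ones, because Ash2l, at -0.2364 (SE 0.1017), lay below its WT level in all 3 KO libraries without passing the test, and gene counts do not show the deleted exons. The Ash2l genotype and a difference in the state of the cultures, which were of the same day per the labels, stay open, and neither was tested apart from the other.

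WT 3 lay apart from WT 6 and WT 7. Its neuronal markers were higher than their mean by a median log2 of 1.63 (22 of 22 genes), its G2/M genes by 1.48 and its hypoxia and glycolysis genes by 0.95, and its astrocyte markers stood at -1.10, each on the KO side. An admixture of cells like those of the KO cultures would lower its oligodendrocyte genes too, but these were higher by a median of 0.4683 (95% bootstrap interval over genes 0.154 to 0.867). That interval does not measure the spread between libraries. The KO libraries themselves differed in this list, with a mean log2 CPM of 3.61, 4.25 and 5.46 in KO 1, KO 2 and KO 3. A small admixture is therefore not excluded. The G1/S genes of WT 3 were higher by a median of 0.21, against 2.56 for KO over WT. WT 6 and WT 7, which differ in sex, correlated more closely (rho 0.9924 across genes) than WT 3 and WT 6 (0.9699), which do not, and thinning to equal depth left WT 3 at 0.3941 of the way from WT 6 and WT 7 to KO on component 1, against 0.393 before, so neither sex nor depth accounts for it. On component 2 KO 3 (25.5) lay on the side of WT 3 (56.7), apart from the other 4 libraries (-23.7 to -16.2), and since the labels do not say what number 3 stands for, a batch shared by that number stays open.

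Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many changed genes (4812, and at most 0 in any other split) and as many lists past the threshold of camera (17, and at most 15 in any other). With 10 splits no share under 0.05 is possible. The other splits called between 10 and 15 lists with the preset correlation. Each of them had more KO libraries on 1 side, so part of the difference between KO and WT remained in it. The preset correlation of 0.01 also lay far below the estimated 0.763 of the G1/S list and 0.932 of the G2/M list. These causes were not told apart, so a camera call with the preset correlation is weak evidence for a list. Each side of these splits held both genotypes, which widened the spread within sides. A count of 0 changed genes there was therefore likely beforehand.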

How the results depend on the processing

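The alternatives with FPKM-implied counts and with a replicate block were chosen after the data were seen, the others before. Genes taken for naming kept their direction in every alternative run, and 96 of 144 kept their call whichever library was left out. As they were picked largely by low p or large change in these data, this does not describe the calls at large. Of all 4812 calls, 44.8%, 49.7% and 51% were kept without WT 6, WT 7 and KO 2. The shares were 57.7%, 76.4% and 93.7% without KO 1, KO 3 and WT 3. Changed genes numbered 4314 to 5589 (4812 as reported) over RLE factors, library totals, both filters, chromosomes left out, both FPKM scales, protein-coding genes only and DESeq2, and 8052 (4133 higher, 3919 lower) with limma-voom, where the cause was not tested, 1522 (751 and 771) against a 1.5-fold change and 1828 (894 and 934) at an adjusted p of 0.01, both stricter by construction. Leaving out 1 library gave 2178 (without WT 6) to 6641 (without WT 3), with 1027 to 3500 higher and 1151 to 3141 lower, and 2449, 2889, 2516 and 4266 without WT 7, KO 1, KO 2 and KO 3. The share of higher genes was 46.6% with TMM, 48.6% with RLE and 51.9% with library totals, and the median of all genes shifted to 0.14 without a filter and 0.16 with DESeq2, which test more low genes. Ash2l stayed between -0.27 and -0.14 without 1 library and passed in no alternative. Of the 11 lists higher and 6 lower, 0 and 0 passed with an estimated correlation, and fry passed 6 higher and 6 lower, including the kinase inhibitors, BMP genes and Wnt mediators, which camera had not passed, but not the radial glia, neuron, immediate early, integrated stress, hypoxia, cholesterol, mitochondrial and pericyte lists (adjusted p = 0.0541 to 0.201). Wnt targets had a median of 0.59 (adjusted p = 0.44, edgeR) with the estimated correlation, and 0.28 to 0.80 without 1 library, the call ending at 0.80 without WT 3 and 0.72 without KO 3. Lists that passed in neither case changed direction in the test, with medians as follows and the cause not tested: dorsal patterning 0.00081 without WT 3 (-0.17 to 0.00081 over libraries left out), ventral patterning 0.31 without X, Y and mitochondrial genes and 0.45 without KO 3 (-0.063 to 0.45), Hedgehog -0.06 without WT 3 and -0.11 without KO 2 (-0.11 to 0.12), ribosomal proteins 0.013 without a filter, -0.012 with the block, and 0.04, 0.02 and -0.15 without WT 3, KO 2 and KO 3 (-0.15 to 0.19, which passed without KO 1), and endothelium 0.25 with the 1 CPM filter. At this depth and spread, with 200 of 16606 genes changed, 68% of simulated 4-fold and 27% of 2-fold changes were found, so smaller changes can be missed. With 4812 genes past the threshold the Benjamini-Hochberg cutoff is less strict than in the simulation, so these shares are not those of the real comparison. WT and KO share only replicate number 3, so 1 pair could be blocked, and the replicate block for WT 3 and KO 3 gave 6156 changed genes (3092 higher, 3064 lower, 4764 of the 4812 among them), 11 lists higher and 7 lower (the BMP genes added) and Ash2l at -0.24 (adjusted p = 0.0954).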

Other observations

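The 6 lists and the genes of the next 2 paragraphs, and the test of genes near Ash2l, were chosen after the results were seen. Camera p-values of these lists were adjusted over the 6 alone. As the lists were chosen from these data, the p-values describe them and do not test them.

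DNA repair genes rose with the cell cycle genes. Of 26 genes of the Fanconi anaemia pathway and homologous recombination 18 rose and 0 fell, with a median log2 fold change of 2.16, among them Brca1 (2.96, SE 0.34, from 4.74 ± 2.12 to 36.9 ± 4.31 CPM, SD, n = 3 each). Lysosomal genes fell, 22 of 32 with 1 rising, at a median of -0.78, including the peptidase Tpp1 (-1.39, SE 0.15), the cholesterol transporter Npc1 (-1.41, SE 0.17) and Scarb2 (-1.29, SE 0.16). Adjusted over the list alone, 19 repair genes rose and 0 fell, and 1 lysosomal gene rose and 25 fell. Camera passed both (edgeR, adjusted p = 6.31e-17 and 1.16e-07), though with an estimated correlation neither held (adjusted p = 0.23 and 0.506 with an estimated correlation).

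Of 29 basement membrane and collagen genes 11 rose and 4 fell, with Col18a1 at 3.22 (SE 0.49, and 2.52 without KO 1), Lama5 at 1.10 (SE 0.18) and Col9a1 at -2.69 (SE 0.48), and their mean log2 CPM was 5.28 in KO 1, 3.97 in KO 2 and 3.93 in KO 3 against 3.29 to 3.42 in WT (camera on the edgeR fit, adjusted p = 0.0149, and adjusted p = 0.506 with an estimated correlation). Pericyte and meningeal markers were also highest in KO 1. Of 28 synaptic genes 6 rose and 1 fell, including Gria1 (2.71, SE 0.66, and 3.33 without WT 3) and Syn1 (1.27, SE 0.30), whose calls ended without WT 6, WT 7, KO 1 or KO 2 (adjusted p = 0.00167, edgeR, and adjusted p = 0.506 with an estimated correlation), and these genes too were higher in WT 3 (mean log2 CPM 5.77) than in WT 6 and WT 7 (4.66 and 4.47). Of 22 imprinted genes 6 rose, Mest at 2.09 (SE 0.25) among them, and 2 fell, Peg3 at -0.69 (SE 0.20) among them, whose call ended without WT 6, WT 7, KO 2 or KO 3, and of 18 ciliary genes 1 rose and 3 fell, and neither list passed camera (adjusted p = 0.123 and 0.464, edgeR). Adjusted over the list alone, the counts of higher and lower genes were 18 and 4 for basement membrane and collagen, 11 and 1 for synaptic, 7 and 5 for imprinted and 1 and 3 for ciliary genes.

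Xist counts were 38917, 44431 and 11 in WT 3, WT 6 and WT 7, and 25631, 23632 and 32344 in KO 1, KO 2 and KO 3. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 1657, 2776, 1521 and 658 reads in WT 7, 12, 6, 16 and 8 in KO 1, and 0 in the other 4 libraries.

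The hypothesis that DNA flanking the targeted Ash2l allele, carried over from another strain, may hold a share of the changed genes was tested by position. Within 5 Mb of Ash2l 21 of 65 tested genes had changed (32.3%, against 29% elsewhere), a difference that a two-sided Fisher's exact test did not find (p = 0.584), and since 65 genes can show only a large excess, this leaves the hypothesis open.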
